A study of Oncorhynchus mykiss with 12 samples.

How the data were processed

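The samples were RNA of cultured trout satellite cells from fish of 5 to 10 g, and 200 ng per sample was labelled for 1 array, per the labels' protocols. Cells grew in 10% serum for 3 days before the methionine regimes in 2% serum. The authors deposited 1 scanner table per array, made with Agilent Feature Extraction, per the file headers. Each holds 62964 spots, of which 60800 are not controls, covering 8969 probes of 3216 miRNA names with 4 to 16 spots each. The processed intensity of a spot is background-subtracted by that software and not normalized between arrays, per the file headers. The authors' deposited value table holds intensity values equal to the unsubtracted median spot brightness at 100% of spots on every array. Its column medians lie between 28.0 and 34.0, it is on a linear scale with no centring, and further data processing by the authors is not given in the sources used here.

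Control spots and outlier spots marked by the scanner software (7.88% to 8.72% per array) were left out, and the spots of a probe averaged. Each array was divided by the 75th percentile of the 361 probes well above background on all 12 arrays and brought back to the geometric mean of these percentiles. Values were then floored at 1 intensity unit and put on the log2 scale. The percentile ranged from 63.5 to 438 units. A probe counted as well above background where over 0.5 of its spots were, and was tested if it was so on every array of at least 1 group. This left 690 probes of 365 names, a name being that of the array design without its species prefix. The brightest probe stands for a name. At the level of probes 0 rose and 3 fell in depleted against supplemented, 1 rose and 0 fell in refed against depleted (limma, with 144 names at an unadjusted p under 0.05), and 8 rose and 55 fell in refed against supplemented cells.

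Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, in 1 fit over 12 arrays without covariates, two-sided, with Benjamini-Hochberg adjustment at 0.05 in each comparison. The R package data.table, version 1.17.8, read the files. Where a name was not well above background on any array of a group, "at least" folds set the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own, on the scaled log2 values. Arrays of the bright group entered as measured, also where the probe was not well above background on them. The groups, comparisons, tests, lists and the rule for named miRNAs were set before the data were examined. The rule takes the 12 largest rises and 12 largest falls past the threshold in each comparison. Where fewer than 5 pass, it takes the 5 smallest p in each direction. It always adds miR-210 and the brightest member of each measured myomiR family, and allows list members past the threshold as examples.

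The 12 lists of families cover myomiRs, other miRNAs tied to myoblast differentiation, the miR-17-92 and paralogous clusters, the miR-15/16 group, the let-7 and miR-100/miR-125 clusters, mesenchymal and fibroblast miRNAs, hypoxia and metabolic stress, and blood cell, endothelial, epithelial, neural, and liver and gut miRNAs. miR-125 and miR-214 each stand in more than 1 list. Lists with at least 3 tested families were tested with camera (preset correlation 0.01) over 261 families, each by its brightest tested probe, with adjustment over lists and comparisons. A family counts as fish-annotated if the array carries a probe for it under a zebrafish, medaka, carp, pufferfish, flounder or halibut prefix (139 of 1783 families). This is a property of the array design, which carries no trout-named probe.

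The chain was tested on simulated data for depleted against supplemented cells over 365 names. With independent noise 7.39%, 54.4% and 91.5% of changes of 0.5, 1 and 2 on the log2 scale were recovered, and 0.451% of unchanged names were called. With real residual arrays shuffled between groups 6.14%, 40.4% and 93.4% were recovered and 1.55% of unchanged names called. In such shuffled arrays camera with its preset correlation called 34.3% of list tests with no effect present, against 0.694% with independent noise. Alternatives covered background correction, scaling, filters, probe choice, the fit, array weights, blocks for slide and sample number, and each array left out in turn. The arrays lie on 2 slides, each holding all 3 groups. Slide 1 holds depleted replicate 6, supplemented replicate 5 and refed replicates 3 and 6. Its depleted and supplemented values thus rest on 1 array each.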

Results

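MicroRNAs were measured in cultured rainbow trout satellite cells, the muscle precursor cells isolated from white muscle, on 12 single-colour arrays. After 3 days of growth the cells were held in low-serum medium under 1 of 3 methionine regimes. The depleted group had no added methionine for 72 h (3 arrays), the supplemented group had 100 µM methionine for 72 h (4 arrays), and the refed group had 48 h of depletion followed by 24 h with 100 µM methionine (5 arrays). The labels do not say that the samples of a group came from separate cultures or fish, so p-values measure only the spread between these samples, which may be technical. Between 5.59% and 14.5% of spots per array were well above background, and 0 spots were saturated. The number of arrays limits the precision. Of 365 miRNA names tested, 113 belonged to families with a fish probe on the array and 252 did not.

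The first comparison asked what 72 h without methionine did. miR-210-3p, a miRNA induced by low oxygen in mammalian cells, and miR-133b, a muscle-restricted miRNA, fell in depleted cells. The miR-210-3p probe of zebrafish design (TTAGCCGCTGTCACA) gave a log2 intensity of 2.72 ± 0.73 (SD, n = 3) in depleted and 4.89 ± 0.36 (SD, n = 4) in supplemented cells. It was well above background on 0 of 3 depleted and 3 of 4 supplemented arrays. The measured log2 difference was -2.17 (limma, Benjamini-Hochberg adjusted p = 0.00174). Set against the background bound of the depleted arrays, supplemented cells were 1.98-fold higher. This is not a strict lower limit, as 1 supplemented array entered as measured though not well above background. With depleted arrays raised to this bound, a setting chosen after seeing the data, the log2 difference was -0.98 and did not pass. miR-133b was 5.95 ± 0.63 (SD, n = 3) in depleted and 7.47 ± 0.13 (SD, n = 4) in supplemented cells, a log2 difference of -1.52 (95% interval -2.12 to -0.92; limma adjusted p = 0.0122). For both miRNAs all 3 depleted arrays lay below every supplemented array.

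The other measured myomiRs did not pass in depleted against supplemented cells. miR-1-3p differed by -1.49 (95% interval -2.83 to -0.16), with 1 of 3 depleted arrays below every supplemented array, and miR-206 by -0.87 (95% interval -1.62 to -0.12), with 3 of 3 below (limma adjusted p = 0.532 for each). Without depleted replicate 6 miR-1-3p differed by -0.38. miR-208 and miR-486 were well above background on 0 arrays by any probe, and no miR-499 probe was so on more than 5 arrays. No probe of these families was well above background on every array of a group, so none of them was tested. With 0 rises and 2 falls past the threshold in limma, 26 names had an unadjusted p under 0.05, and over the 261 families 0 rose and 3 fell, miR-210, miR-133 and miR-6366 (limma adjusted p = 0.0390 for the last). With miR-210-3p at its bound 1 family fell, miR-133. The miR-6366 call was kept in 4 of 12 fits that each left out 1 array, and lost without depleted replicate 6, any 1 supplemented array, or refed replicate 2, 5 or 6. None of the following passed over the 365 names. Those with the smallest p among higher values were miR-513a-5p (0.74), miR-1306-3p (0.91), miR-553 (1.85), miR-378b (0.71) and miR-5787 (0.97). As miR-553 was not well above background on any supplemented array, depleted cells can be given only as at least 1.09-fold higher for it. Those among lower values, after the called pair, were miR-6366 (-1.49), miR-5100 (-0.91) and miR-652-5p (-0.78). Without depleted replicate 6 miR-1306-3p, miR-5787 and miR-6366 were 0.39, 0.23 and -0.93.

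With slide as a block the differences were -2.15 for miR-210-3p and -1.50 for miR-133b. They were -2.85 and -2.01 within slide 1, and -1.81 and -1.27 within slide 2. With depleted arrays at the bound miR-210-3p was -0.55 within slide 1 and -1.18 within slide 2. The values within slide 1 set depleted replicate 6 alone against supplemented replicate 5 alone. The miR-210-3p call was lost in 7 of 36 alternatives, among them normexp (-0.53), the authors' values (-0.75), total gene signal (-1.92) and no scaling (-1.88), and that of miR-133b in 13 of 37, among them those without depleted replicate 5 (-1.43), depleted replicate 6 (-1.24) or supplemented replicate 6 (-1.47). The count of 2 was 1 without depleted replicate 6 and 1 without supplemented replicate 6.

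**Figure D1:**
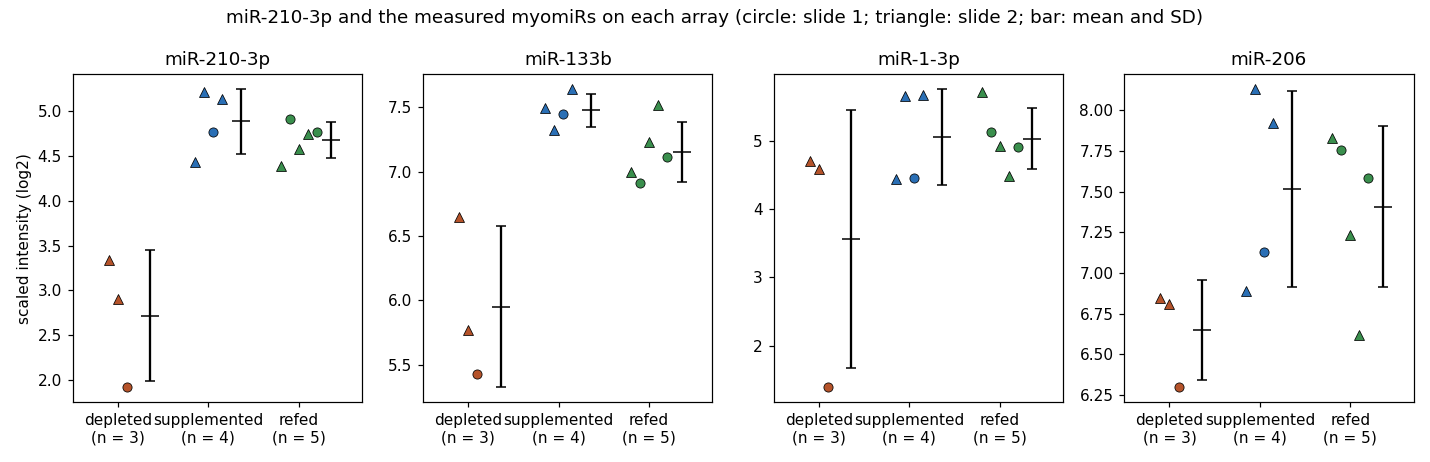
Scaled log2 intensity (vertical axis) of miR-210-3p, miR-133b, miR-1-3p and miR-206 on each of 12 arrays, by group; circles are arrays of slide 1, triangles arrays of slide 2, and bars give the group mean and SD. All 3 depleted arrays lie below all 4 supplemented arrays for miR-210-3p, miR-133b and miR-206, and depleted replicate 6 is the lowest point of each panel.

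Among miRNA lists fixed beforehand, the 3 measured myomiR families lay below 0 in depleted minus supplemented cells (mean log2 -1.29). Of these, miR-133 passed over all 261 families, and 3 passed adjusted over the list alone. In the hypoxia and metabolic-stress list 3 of 3 tested families lay below 0 (median -0.45, mean -1.004), and miR-210 alone passed, as it did adjusted over the list alone. Of 13 families tied to myoblast differentiation 12 lay below 0 (mean -0.30), with 0 past the threshold in limma and 0 adjusted over the list alone. Camera with a preset correlation called these 3 lists (Benjamini-Hochberg adjusted p = 9.61e-05, 0.000696 and 0.00815). With an estimated correlation none held (camera adjusted p = 0.134, 0.144 and 0.374). The myomiR list alone passed with fry, another list test, and with camera within fish families (adjusted p = 0.0424 and 0.0387). The last of these tests was chosen after seeing the data. Over single names the median difference was -0.28 with a fish probe in the family and 0.18 for the rest. Without depleted replicate 6 the list means were -0.76, -0.61 and 0.11, the last not called. The differentiation mean was -0.57 without depleted replicate 2, and the list was not called without supplemented replicate 4 (-0.26) or 6 (-0.23). With miR-210 at its bound the hypoxia mean was -0.61. With slide as a block the 3 means were -1.25, -0.99 and -0.27, within slide 1 -1.97, -1.41 and -0.79, and within slide 2 -0.90, -0.75 and -0.012. The miR-17-92 (mean -0.29), let-7 and miR-100/miR-125 (mean -0.32) and mesenchymal (median -0.036) lists were not called (camera adjusted p = 0.0856, 0.152 and 0.728), with 0 families past the threshold in limma or adjusted over the list alone. Without depleted replicate 2 the miR-17-92 and let-7 lists were called (means -0.55 and -0.69), and the miR-17-92 list also without supplemented replicate 5 (-0.51) or refed replicate 5 (-0.33). None of these 4 calls held, with adjusted p = 0.225 at the lowest and adjusted p = 0.483 at the highest with an estimated correlation. Without depleted replicate 6 these means were 0.042 and 0.25. The 3 means were -0.26, -0.28 and 0.018 with slide as a block, and without scaling the miR-17-92 and mesenchymal means turned to 0.0047 and 0.29.

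The second comparison set cells given methionine back for the last 24 h against cells depleted for 72 h. No group was sampled at 48 h of depletion. A rise on refeeding thus cannot be told apart from a fall that came only after 48 h in depleted cells. Rises and falls here mean higher and lower values in refed cells. miR-210-3p was higher, at 4.68 ± 0.20 (SD, n = 5) in refed against 2.72 ± 0.73 (SD, n = 3) in depleted cells. In refed cells it was well above background on 5 of 5 arrays. The measured log2 difference was 1.96 (limma, Benjamini-Hochberg adjusted p = 0.00333), and all 5 refed arrays lay above every depleted array. Refed cells were at least 1.71-fold higher. With depleted arrays at the bound the log2 difference was 0.77, which did not pass over the 365 names but did over the 261 families. Without depleted replicate 6 the difference at the bound was 0.89 and passed. In the main fit miR-210-3p was the only name past the threshold, with 0 falls in limma, while 144 names had an unadjusted p under 0.05. Over the 261 families 12 rose and 40 fell, but of these 52 calls the count became 1 without depleted replicate 5, supplemented replicate 2 or refed replicate 2, 4 or 6, and 2 without refed replicate 3. miR-133b differed by 1.20 (95% interval 0.63 to 1.78), with 5 of 5 refed arrays above every depleted array (limma adjusted p = 0.0545). It passed with some alternatives, among them without depleted replicate 2 (1.55), depleted replicate 6 (0.90) or supplemented replicate 5 (1.21) and with slide as a block (1.22). miR-1-3p differed by 1.47 and miR-206 by 0.76, each with 4 of 5 above (limma adjusted p = 0.0864 and 0.108), though miR-1-3p turned to -0.15 with normexp and was 0.34 without depleted replicate 6, and miR-206 passed with all probes as reference (1.29) and with array weights (0.73).

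In refed against depleted cells 73 names had a limma adjusted p under 0.06. This count includes the called name, and the others lay just outside the threshold. Those with the smallest p among higher values were miR-133b, miR-29c-3p (1.10), miR-221 (1.02) and miR-27b-3p (1.18, and 0.74 without depleted replicate 6). Those among lower values were miR-1228-5p (-1.02), miR-466d_v20.0 (-0.97), miR-378b (-1.06), miR-10d (95% interval -1.56 to -0.44) and miR-669l-5p (-0.93); without scaling the last of these was 0.020. None of these passed over the 365 names, while the families of all but miR-10d passed over the 261 families. Of names with an unadjusted p under 0.05, 57 with a fish probe in the family were higher and 4 lower, against 1 higher and 82 lower among the rest.

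The composition index of an array, the mean log2 of names with a fish probe in the family (miR-210 left out) minus that of the rest, was 0.69 ± 0.33 (SD, n = 5) in refed, -0.07 ± 0.56 (SD, n = 4) in supplemented and -0.46 ± 0.82 (SD, n = 3) in depleted cells. The two-sided exact permutation p was 0.0179 for refed against depleted, 0.0476 for refed against supplemented and 0.457 for depleted against supplemented cells. On depleted replicates 2, 5 and 6 the index was 0.19, -0.19 and -1.38, so the depleted mean leans on replicate 6. The difference of refed minus depleted cells in the index was 1.18 with slide as a block, 2.28 within slide 1, where replicate 6 is the only depleted array, and 0.54 within slide 2. That of refed minus supplemented cells was 0.83, 1.69 and 0.37.

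The miR-210-3p difference of refed minus depleted cells was 1.98 with slide as a block, 2.92 within slide 1 and 1.45 within slide 2, and with depleted arrays at the bound 0.76, 0.62 and 0.82; with the composition index as a covariate, chosen after seeing the data, it was 1.28 and not past the threshold. The call was lost in 7 and reversed in 1 of 36 alternatives, among them normexp, where the difference turned to -0.13, the authors' values (0.14), total gene signal (2.18) and no filter (1.96). The count of 1 call became 94 with slide as a block (39 rises, 55 falls), 71 without depleted replicate 2, 72 without depleted replicate 6 and 34 without supplemented replicate 5. The split also moved with scaling, to 2 rises and 103 falls with fish families as reference and 76 rises and 0 falls with all probes as reference.

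**Figure D2:**
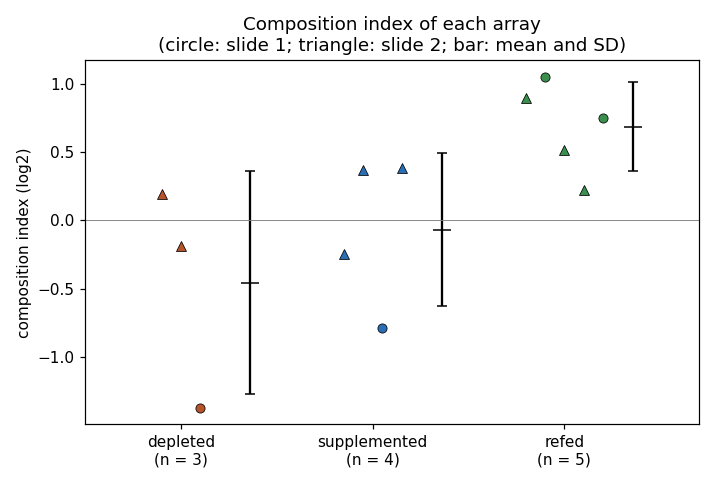
Composition index (log2, vertical axis) of each of 12 arrays by group; circles are arrays of slide 1, triangles arrays of slide 2, and bars give the group mean and SD. Depleted replicate 6 lies lowest at -1.38, and the 5 refed arrays lie between 0.22 and 1.05.

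In refed minus depleted cells the median difference was 0.76 over names with a fish probe in the family and -0.47 over the rest. Most listed families have a fish probe, and all 6 lists with enough tested families had means above 0. They were 1.14 for the myomiRs, 0.84 for let-7 and miR-100/miR-125, 0.75 for miR-17-92 and its paralogs, 0.66 for differentiation, 0.43 for the mesenchymal list (-0.090 when scaled on fish families) and 1.03 for the hypoxia list (-0.14 with normexp). With the composition index as a covariate the let-7, miR-17-92, differentiation and mesenchymal means turned to -0.24, -0.053, -0.0069 and -0.095. No list was called there. Families with a fish probe enter the index, so part of this fall follows by construction. In the main fit camera with a preset correlation called each of the 6 lists (Benjamini-Hochberg adjusted p between 2.78e-07 and 0.00166). With an estimated correlation none held (camera adjusted p = 0.144 at the lowest and 0.157 at the highest). Within fish families none was called either (camera adjusted p between 0.604 and 0.826), with the mesenchymal list down. Fry called the myomiRs and the hypoxia list (adjusted p = 0.0424 for each). Over all families miR-133 rose among the myomiRs, miR-210 in the hypoxia list, and miR-17 and miR-20 in the miR-17-92 list. In the differentiation list miR-27 (1.35), miR-29 (1.10), miR-221, miR-26 and miR-128 rose and miR-378 fell by 1.06 (limma, adjusted over 261 families). Of these families miR-210 was called in 12 of 12 fits that each left out 1 array and the others in 1 to 7, none of them without depleted replicate 5, supplemented replicate 2 or refed replicate 2, 4 or 6. Among them miR-210 alone changed sign under another scaling or background setting, at -0.13 with normexp. Of 9 settings, the main one included, miR-128 passed in 2 and miR-17 and miR-20 in 3 each. Without depleted replicate 6 the means were 0.59 for the myomiRs, 0.25 for let-7, 0.41 for miR-17-92, 0.23 for differentiation, 0.21 for the mesenchymal and 0.62 for the hypoxia list, which was 0.63 with miR-210 at its bound. Adjusted over the list alone 3 myomiR, 9 differentiation, 5 miR-17-92, 2 let-7 and miR-100/miR-125, 2 mesenchymal and 1 hypoxia-list families passed. With slide as a block the list means lay between 0.44 and 1.17, within slide 1 between 0.85 and 2.19 and within slide 2 between 0.20 and 0.61, beside the index differences given above.

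The third comparison set refed cells against cells that had methionine throughout. miR-29a-3p and miR-29c-3p, of a family that targets collagen transcripts in mammals, rose by log2 differences of 1.08 and 1.05, and miR-15a rose by 1.18 (limma, Benjamini-Hochberg adjusted p = 0.0487, 0.0336 and 0.0336), each with 5 of 5 refed arrays above every supplemented array. With normexp the differences of miR-29a-3p and miR-15a turned to -0.13 and -0.094. miR-205-5p, a miRNA of epithelia, fell by 1.61 on the log2 scale, with 5 of 5 refed arrays below every supplemented array (limma adjusted p = 0.0336). miR-210-3p differed by -0.21 (95% interval -0.80 to 0.38), with 1 of 5 refed arrays below every supplemented array (limma adjusted p = 0.633), though with normexp and the authors' values it passed, at -0.66 and -0.62, and it was 0.0023 with quantile normalization, 0.26 with total gene signal, 0.37 with all probes as reference and 1.04 without scaling. Relative to the median difference of all names, miR-210-3p was -0.16 with normexp and -0.18 with the authors' values. Its difference was -0.17 with slide as a block, within slide 1 0.071 and within slide 2 -0.35. miR-133b (-0.32), miR-206 (-0.11) and miR-1-3p (-0.03) did not pass. With all probes as reference these were 0.26, 0.47 and 0.55, and without scaling 0.92, 1.13 and 1.22. miR-1-3p passed with normexp (-0.54, but -0.038 relative to the median of all names) and with the composition index as a covariate (-1.29).

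In refed against supplemented cells 3 names rose and 31 fell, and 108 had an unadjusted p under 0.05. Over the 261 families 4 rose and 17 fell; these 21 calls became 0 in limma without any 1 of supplemented replicates 2 and 6 and refed replicates 2, 3, 4 and 6 (57 to 75 families at an unadjusted p under 0.05), 5 without supplemented replicate 5, 32 without supplemented replicate 4 and 58 without depleted replicate 6. Of the 31 falls 30 were names with no fish probe in the family. The largest of these 30 were miR-548aj-3p (-1.38), miR-1260a (-1.31), miR-574-3p (-1.29), miR-1281 (-1.29), miR-548x-3p (-1.27) and miR-466g (-1.27), followed by miR-548ap-3p, miR-466b-3p, miR-4690-5p, miR-548c-3p and miR-3162-3p, between -1.23 and -1.17, which turned to between 0.011 and 0.077 without scaling. The limma adjusted p of these names lay between 0.0336 and 0.0413, each with 4 or 5 of 5 refed arrays below every supplemented array. The median difference was 0.39 over names with a fish probe in the family and -0.34 over the rest, beside a composition index that was 0.76 higher in refed cells and a 75th percentile of signal that was 1.24 higher on the log2 scale (two-sided exact permutation p = 0.0476 and 0.0397).

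The count of 34 rests on single arrays. It was 0 in limma without any 1 of 6 arrays (supplemented replicates 2 and 6, and refed replicates 2, 3, 4 and 6), with 78 to 99 names at an unadjusted p under 0.05, and 100 without depleted replicate 6. Without supplemented replicate 5 miR-15a (0.97), miR-29a-3p (0.78) and miR-29c-3p (0.90) were not past the threshold either, nor were miR-29a-3p and miR-29c-3p (0.95) without refed replicate 5. With slide as a block 44 names passed and in slide 2 alone 0 did in limma (93 at an unadjusted p under 0.05); miR-15a was 1.24 with the block, 2.14 in slide 1 alone and 0.87 in slide 2 alone. These values were 1.16, 2.29 and 0.69 for miR-29a-3p, 1.06, 2.00 and 0.71 for miR-29c-3p, and -1.59, -0.24 and -2.11 for miR-205-5p. By scaling there were 0 calls in limma with the median of detected probes (93 at an unadjusted p under 0.05), 3 rises and 8 falls with quantile normalization, 2 rises and 80 falls with fish families, 22 rises and 0 falls with all probes, and 75 rises and 0 falls without scaling.

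The reference for scaling moved the median difference of all names from -0.48 to 1.08 in refed minus supplemented, from -0.78 to 0.69 in refed minus depleted and from 0.032 to 0.33 in depleted minus supplemented cells. Scaling each array by 1 factor leaves differences relative to that median as they are by construction. Over these settings, quantile normalization, normexp, the authors' values and total gene signal, miR-210-3p relative to the median lay between -2.36 and -0.44 in depleted minus supplemented and between 0.32 and 2.45 in refed minus depleted cells. miR-133b lay between -1.61 and -0.79 and between 1.03 and 1.47. In refed minus supplemented cells miR-29c-3p lay between 1.11 and 1.26, miR-15a between 0.41 and 1.78, miR-29a-3p between 0.37 and 1.44, and miR-205-5p between -1.59 and -0.64 relative to it.

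In refed minus supplemented cells the differentiation, mesenchymal, miR-17-92, and let-7 and miR-100/miR-125 lists had means of 0.36, 0.43, 0.46 and 0.52. With the composition index as a covariate the differentiation, miR-17-92 and let-7 means turned to -0.083, -0.069 and -0.19, and no list was called. Most families of these lists have a fish probe and enter the index, so part of this fall follows by construction. In the main fit camera with a preset correlation called these 4 lists (Benjamini-Hochberg adjusted p = 0.000114, 0.000696, 0.000696 and 0.00696). With an estimated correlation none held (camera adjusted p = 0.184, 0.144, 0.184 and 0.218). Within fish families none was called either (camera adjusted p = 0.604, 0.604, 0.613 and 0.629). Over all families miR-27 and miR-29 of the differentiation list rose, calls kept in 4 and 5 of 12 fits that each left out 1 array and lost without supplemented replicate 2, 5 or 6 or refed replicate 2, 3, 4 or 6 (miR-27 also without refed replicate 5), and 0 families of the other 3 lists passed in limma; adjusted over the list alone 2, 0, 1 and 0 did. Without supplemented replicate 5 the miR-17-92 mean was 0.25 and the let-7 list (0.38) was not called. With slide as a block the means were 0.41, 0.46, 0.51 and 0.59, within slide 1 0.74, 0.91, 1.33 and 1.03, and within slide 2 0.20, 0.24, 0.10 and 0.32. The myomiRs (mean -0.15, while the direction given by camera was up) and the hypoxia list (mean 0.024) were not called (camera adjusted p = 0.841 and 0.407), with 0 families past the threshold in limma or adjusted over the list alone. The myomiR mean turned to 1.09 without scaling and the hypoxia mean to -0.47 with normexp, and with slide as a block they were -0.080 and 0.054.

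Over the 3 groups together, the moderated F test of limma called 2 names, miR-210-3p (Benjamini-Hochberg adjusted p = 0.00277) and miR-133b (adjusted p = 0.0341). With depleted arrays at the bound for miR-210-3p it called 0, with 133 names at an unadjusted p under 0.05. The count was 64 without depleted replicate 2, 125 without depleted replicate 6, 62 without supplemented replicate 4 and 27 without refed replicate 5. It was 1 without depleted replicate 5, supplemented replicate 6 or any 1 of refed replicates 2, 3, 4 and 6. Across the 365 names, which are not independent replicates, the depleted minus supplemented and refed minus supplemented differences correlated at r = 0.066, with a covariance of 0.0178. Unchanged groups simulated against the same supplemented arrays gave a mean r of 0.461 and a mean covariance of 0.0676, and 833 of 1000 simulations reached the observed r. With the supplemented arrays split 2 and 2, r lay between -0.417 and 0.411. A shared effect was not detectable with these arrays.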

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

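The tests of the composition index, depleted replicate 6, the background bound, slide and quantile normalization were chosen only after the result was seen; those of GC content and of other splits of the samples were set before. The bar for the composition and quantile tests on refed against supplemented cells was changed 3 times after their results were seen, and is now that of the GC test, which was set before. The miR-210-3p tests were also moved to the background bound after the measured values were seen. The bar for those of composition, depleted replicate 6 and slide was then changed once more. It now asks for a kept call as measured and a difference at the bound of over 2 standard errors, where the earlier bar asked for an adjusted p under 0.05 at the bound.

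Of 74 groups of 4 or 5 values examined, 3 held a sample far from the others, and chance flags about 1 in 20 groups. miR-1306-3p was 4.62 on the log2 scale in refed replicate 3, against 4.84 to 4.92 on the other refed arrays. miR-1228-5p was 3.89 in supplemented replicate 4, against 4.41 to 4.49 on the other supplemented arrays. miR-466d_v20.0 was 3.93 in supplemented replicate 4, against 4.37 to 4.44 on the others.

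miR-210-3p and miR-133b were lower in depleted than in supplemented cells. For miR-133b the composition of the array signal as the whole cause is argued against by a difference of -1.44 with the index as a covariate, past the threshold (limma adjusted p = 0.0150, in a range of 3.22e-06 to 0.962 over all alternatives), while its call ended without depleted replicate 6 (-1.24). For miR-210-3p the measured differences were past the threshold, -1.94 (SE 0.227) with the covariate and -1.74 without depleted replicate 6. At the bound they were -0.98 (SE 0.233) and -1.11 (SE 0.285), and neither passed (limma adjusted p = 0.116 and 0.201). Only under the bar changed after results were seen do these values argue against composition and depleted replicate 6 as the whole cause. Under the earlier bar they could not tell. Nearness to background cannot be told apart from the regime, since at the bound no difference passed (-0.98, SE 0.256, without correction). For the count of 2 calls chance could not be excluded: 3 of 35 splits gave at least as many, and the highest other split gave 47 (depleted replicate 6 with supplemented replicates 2 and 5), which points to a structure of the samples. An effect of methionine stays open as a hypothesis, as do the miR-210-3p calls lost with other settings, among them other background handling, scaling or signal (-1.92 to -0.53).

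miR-210-3p was higher in refed than in depleted cells. Slide as the whole cause is argued against by a difference of 0.76 (SE 0.248) with slide as a block and depleted arrays at the bound, past the threshold, and by 0.62 and 0.82 within the slides. The value of 0.62, within slide 1, rests on depleted replicate 6 as the only depleted array. The composition of the array signal and the regime cannot be told apart: with the index as a covariate the measured difference went from 1.96 (SE 0.303) to 1.28 (SE 0.286) and was no longer past the threshold, while at the bound it was 0.77 (SE 0.245) and 0.78 (SE 0.294). For the count of 1 call, 1 of 56 splits, the real one, reached it and the highest other gave 0, but the call rests on depleted values below background, and at the bound miR-210-3p passed over the 261 families and not over the 365 names, so chance is not excluded by these splits. The reversed sign with normexp (-0.13) came beside a median difference of all names of -0.45, relative to which miR-210-3p stayed higher (0.32). Normexp adds 50 units before scaling, so values of dim probes move with the scaling factor of their array. An effect of methionine is a hypothesis. With no group sampled at 48 h of depletion, a rise on refeeding cannot be told apart from a later fall in depleted cells.

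Names with no fish probe in the family made up 30 of the 34 calls between refed and supplemented cells. A trend on the GC content of the probe as the whole cause is argued against by 24 of the 34 calls that remained once it was removed from each array. The brightness of the arrays stays open as a cause, with 11 of these calls left after quantile normalization. Their composition cannot be told apart from the regime, with 17 of the 34 left under the covariate. All calls of the covariate fit numbered 31, of which 28 had no fish probe in the family. This was 8 of 11 with quantile normalization and 33 of 51 with the GC trend removed, beside 252 of all 365 tested names. Binding of other RNA to mammalian probes was not tested, and an effect of the regime is a hypothesis. The 30 names, picked by their calls, had a median of -1.13 (median SE 0.301), then -1.16 (0.327) with the covariate, where 14 of 17 lost calls had a smaller difference and 9 a larger error, and -0.99 (0.276) with quantile normalization, where 23 of 23 had a smaller difference and 2 a larger error, while the median of names with a fish probe went from 0.39 to -0.20 and 0.52. For the count of 34, 2 of 100 drawn splits reached it, the real one and 1 other, a share below the bar set before. The other one gave more calls, 45 (the supplemented arrays and refed replicate 5 against the other refed arrays). The count was also 0 without any 1 of supplemented replicates 2 and 6 and refed replicates 2, 3, 4 and 6. Chance is thus not taken as excluded by these splits, and a structure of the samples stays open.

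For the 2 calls over all 3 groups chance could not be excluded, with 6 of 100 drawn splits reaching that count and 116 in the highest other, which points to a structure of the samples.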

How the results depend on the processing

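The alternatives with fish families as reference or as the tested set, total gene signal, either slide alone, the composition covariate, miR-210-3p at its background bound, depleted 6 and supplemented 2 left out, and camera within fish families were chosen after seeing the data. Signal over background limits what is known of miR-210-3p, which was not well above background on depleted arrays, and is not tested where every array had to be above background. Slide as a random block was not run, since each slide holds all groups. Except where a clause below gives it, the cause was not tested. Counts are given in the order depleted minus supplemented (2), refed minus depleted (1), refed minus supplemented (34) and any difference (2), and called lists numbered 3, 6 and 4. miR-210-3p kept its call in 29 of 36 alternatives in depleted minus supplemented and 28 of 36 in refed minus depleted cells. Where a comparison had 0 calls in limma, between 2 and 315 names had an unadjusted p under 0.05.

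With normexp the counts were 0, 96, 176 and 164, with 1 list for depleted minus supplemented cells. Normexp adds 50 units before scaling, so values of dim probes move with the scaling factor of their array. With it the median difference of all names was -0.45 in refed minus depleted and -0.50 in refed minus supplemented cells. There miR-210-3p was -0.53, -0.13 and -0.66, the hypoxia list in refed minus depleted cells turned to -0.14, and miR-15a and miR-29a-3p in refed minus supplemented cells turned to -0.094 and -0.13. With the authors' values the last 3 counts were 96, 133 and 137, and miR-210-3p was -0.75, 0.14 and -0.62. With depleted arrays at the bound, which narrows its differences by construction, miR-210-3p was -0.98 and 0.77, and the counts were 1, 0 (144 names at an unadjusted p under 0.05 in limma), 34 and 0. Quantile normalization gave 3 and 11 for the refed comparisons, and the median of detected probes 2 and 0. The percentile over all probes gave 1, 76, 22 and 60. No scaling gave 0, 75 and 35 for depleted minus supplemented, refed minus supplemented and any difference, with miR-210-3p at -1.88; there miR-548ap-3p, miR-466b-3p, miR-4690-5p, miR-548c-3p and miR-3162-3p in refed minus supplemented cells turned to 0.011, 0.035, 0.042, 0.049 and 0.077.

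With no filter the first 3 counts were 5, 2 and 0, r between effects was 0.398, and miR-210-3p in refed minus depleted cells stayed at 1.96 but missed the threshold as 3216 names were tested. With only probes above background on all arrays 47 and 52 names passed for refed minus depleted and any difference, 1 list for depleted minus supplemented, and r was 0.250. The median over probes gave 10 for any difference, and every probe as a unit gave 63 for refed minus supplemented and 1 for any difference. Slide as a block gave 94 for refed minus depleted. Only the 2 groups compared gave 1 and 67 for the comparisons with supplemented cells. Trend and robust gave 28 for refed minus depleted, and array weights 132, 118 and 151 for the last 3 counts.

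The labels do not say whether equal sample numbers mark shared cultures or fish, and the main fit did not pair them. Of 10 same-numbered pairs 2 had deviations correlated above 0.1 (range -0.51 to 0.409). With so few arrays per group this cannot settle whether the samples were paired. With the replicate block the 4 counts were 0 in limma, with 24, 63 and 90 names at an unadjusted p under 0.05 in the first 3, and miR-210-3p was -2.12 and 1.86 in the first 2 comparisons. With slide and replicate block together the 4 counts were again 0, with 40, 102 and 112 names at an unadjusted p under 0.05, and miR-210-3p was -2.12 and 1.86.

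With fish families for scaling the counts were 1, 105, 82 and 110, and the mesenchymal list in refed minus depleted cells turned to -0.090. With only fish families tested refed minus supplemented had 0 calls, and lists numbered 1, 0 and 0. With both the last 3 counts were 2, 3 and 4, lists again 1, 0 and 0, and the mesenchymal mean -0.090. Total gene signal gave 0 for refed minus depleted and any difference, miR-210-3p at -1.92 and 2.18, and r = 0.327. Slide 2 alone gave 1, 28, 0 and 0, 2 lists for refed minus supplemented, r = 0.457, and 0.0060 for the differentiation list in depleted minus supplemented cells, a turned sign. Slide 1 alone rests on 1 depleted, 1 supplemented and 2 refed arrays, the lone samples being assumed to vary like the refed pair; it gave 130, 254, 181 and 290 and r = -0.149. With the composition covariate refed minus depleted had 0 calls and miR-210-3p at 1.28, any difference 9, and both refed comparisons 0 lists. There the let-7, mesenchymal, differentiation and miR-17-92 means turned to -0.24, -0.095, -0.0069 and -0.053 in refed minus depleted cells. The let-7, differentiation and miR-17-92 means turned to -0.19, -0.083 and -0.069 in refed minus supplemented cells. Most families of these lists enter the index, so part of this follows by construction. Without depleted 6 and supplemented 2 the last 3 counts were 73, 8 and 88, r was 0.256, and the differentiation mean in depleted minus supplemented cells turned to 0.10. Camera with an estimated correlation called 0, 0 and 0 lists, fry 1, 2 and 0, the mixed test of fry 0, 0 and 0, and camera within fish families 1, 0 and 0. The lists called by fry were the myomiRs in the first comparison, and the myomiRs and the hypoxia list in the second. The list called within fish families was that of the myomiRs. Over 3 splits of the supplemented arrays, 2 and 2, r averaged -0.041 (lowest -0.417, highest 0.411), and -0.157 in 1 of them.

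Leaving out each of 12 arrays in turn gave counts of 1 to 3, 1 to 72, 0 to 100 and 1 to 125, lists of 2 to 5, 6 to 7 and 3 to 5, and r of -0.079 to 0.371. miR-210-3p lay between -2.48 and -1.74 in depleted minus supplemented and between 1.52 and 2.27 in refed minus depleted cells, past the threshold in 12 of 12, and between -0.37 and -0.098 in refed minus supplemented cells, past it in 0 of 12 with limma. The differentiation mean in depleted minus supplemented cells lay between -0.57 and 0.11 (without depleted replicate 6). Of the arrays left out 6 gave 0 calls in refed minus supplemented cells in limma, with 78 to 99 names at an unadjusted p under 0.05, and depleted replicates 2 and 6 and supplemented replicate 5 gave 71, 72 and 34 in refed minus depleted cells.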

Other observations

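Markers of other cell types were mostly not well above background: 0 of 7 neural families were tested, and 1 family each in 4 other lists. Those were miR-150 of blood cells, miR-10 of endothelium, miR-205 of epithelia and miR-194 of liver and gut. Their log2 differences were 0.25, -0.47, -1.13 and -0.16 in depleted minus supplemented, -0.41, 1.32, -0.48 and -0.36 in refed minus depleted, and -0.15, 0.85, -1.61 and -0.51 in refed minus supplemented cells. Of the miR-10 family, miR-10d differed the other way in refed minus depleted cells (95% interval -1.56 to -0.44, 5 of 5 refed arrays below every depleted array) from miR-10a-5p (0.98), miR-10b (1.17) and miR-10b-5p (1.32), none past the threshold. Over all 261 families only miR-205 in refed minus supplemented cells passed in limma with Benjamini-Hochberg adjustment, a call lost without supplemented replicate 2 or 6 or refed replicate 2, 3, 4 or 6. Adjusted over the list alone, which for 1 family is its unadjusted p, miR-205 also passed in depleted minus supplemented, miR-10 in refed minus depleted and miR-194 in refed minus supplemented cells. In the miR-15/16 group miR-15 and miR-16 were tested, at 0.96 and 1.57 in refed minus depleted cells, where miR-15 passed over all families (but was -0.0061 with normexp, and was called in 4 of 12 fits that each left out 1 array, none of them without depleted replicate 5 or 6, supplemented replicate 2 or 6 or refed replicate 2, 3, 4 or 6) and 2 passed adjusted over the list alone. In refed minus supplemented cells miR-15 passed both ways (1.18, but -0.094 with normexp, and over all families not without supplemented replicate 2, 5 or 6 or refed replicate 2, 3, 4 or 6), and in depleted minus supplemented cells 0 did in limma, over all families or adjusted over the list alone.

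A further 3 probes for miR-210-3p, the others that were well above background on any array, also gave lower means in depleted cells. The shorter zebrafish probe gave scaled intensities of 2.14 ± 1.27 (SD, n = 3) in depleted, 16.1 ± 3.55 (SD, n = 4) in supplemented and 13.6 ± 1.61 (SD, n = 5) in refed cells. A carp probe gave 6.43 ± 1.09 (SD, n = 3), 14.3 ± 4.27 (SD, n = 4) and 14.5 ± 1.29 (SD, n = 5), and a human probe 2.43 ± 1.13 (SD, n = 3), 7.65 ± 2.89 (SD, n = 4) and 7.36 ± 1.03 (SD, n = 5). These probes overlap in sequence, were well above background on 5, 5 and 3 of 12 arrays, and were not tested. The remaining miR-210-3p probes were well above background on 0 arrays and went both ways between depleted and supplemented cells. A shorter carp probe gave 2.58 and 1.55 and a medaka probe -1.80 and -2.13, while a shorter human probe gave -0.23 and 0.37 and another medaka probe -3.06 and -2.50. The miR-210-5p probes were well above background on 0 arrays.

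A hypothesis whose test was set before the result was seen was that miR-210-3p varies with the myomiRs from array to array within groups. Its deviations from the group means correlated with those of the mean of miR-1-3p, miR-133b and miR-206 over 12 arrays (r = 0.839, permutation p = 0.0332; Spearman's rho = 0.867, permutation p = 0.0224), the only pair of measures related. The relation rests on depleted replicates 2 and 6: without these r was 0.564 over 10 arrays, with a permutation p of 0.201 that was computed only after the result was seen. The miR-210-3p probe was not well above background on the 3 depleted arrays and 1 supplemented array; over the 8 others r was 0.251 (exact permutation p = 0.612; Spearman's rho = 0.214, exact permutation p = 0.656), also computed only after the result was seen. Within slide 2 r was 0.725 over 8 arrays, and slide 1 holds 4, too few for a correlation. With the composition index removed r was 0.503 (permutation p = 0.141). miR-1-3p, miR-133b and miR-206 are among the 113 names with a fish probe in the family and enter the index, so part of this fall follows by construction. A link cannot be told apart from the composition of the array signal, and the relation over 12 arrays rests on depleted values at background level.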
